A study of Mus musculus with 8 samples.

How the data were processed

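A set of 8 one-colour Agilent mouse expression arrays were analysed, 1 per RNA sample: 1 of an embryonic stem cell (ESC) line, 4 of OSKH induced pluripotent stem cells (iPSCs) and 3 of OSK iPSCs. Groups and array numbers were taken from the sample titles. The labels do not say whether arrays of a group are separate lines, clones or cultures, so p-values measure only the spread between these samples, which may be technical. All 8 arrays lay on 1 slide, with ESC and OSKH 1 to 3 in slide row 1 and OSKH 4 and OSK 1 to 3 in slide row 2, per the file headers. Arrays of the same number in both iPSC groups, 1 to 3, also shared a slide column, and OSKH 4 shared a column with ESC.

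Per the labels, total RNA was amplified and labelled with Cy3. Per the file headers, the spots were quantified by Agilent Feature Extraction 11.5.1.1, and the deposited intensity of each spot is a processed signal, background-subtracted and detrended within the array but not scaled between arrays. The flags in the same deposited files (well above background, saturated, outlier) are 0 or 1. The series also has a deposited value table on a log2 scale, and its columns equalled the log2 processed signal minus 1 constant per array, to within 0.01 for at least 99.7% of probes. Its column medians ran from -3.71 to -3.60. Its scale, its lack of centring per gene and its direction were thereby settled, while the software that made it is not given in the sources used here. The probe annotation of the array refers to mouse genome build mm9, per the file headers, and no coordinates are reported.

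Of each array, 59305 spots other than controls were used, and the 3671 control spots were left out. Spots with a non-uniformity or population outlier flag were left out and the rest averaged per probe, which gave 55681 probes, of which 14 had no unflagged spot on some array and were dropped. The main value was the log2 processed signal minus the 75th percentile of its array, so that 0 is the level of the 75th percentile. Saturated probes would have been kept, and there were 0. A probe was tested if it was well above background on at least 3 of 8 arrays. A gene expressed on the ESC array alone could therefore not be tested. The files give accessions and no gene names. RefSeq accessions were matched, without versions, to current symbols in a table of assembly GRCm38.p6, which named 27650 probes, while 28017 kept the identifier in the file. For each gene the probe with the highest mean over all arrays was used. This left 22685 features, 14393 of them named genes. Of 3671 genes with several probes that passed the filter, 16 had probes whose OSKH minus OSK differences lay over 1 log2 unit apart.

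Between 51.4% and 59.0% of probes were well above background, and the 75th percentile of the signal ran from 424 to 501 across arrays. The number of arrays limits the precision of every comparison.

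The 3 groups were compared in limma 3.58.1 under R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The fit had 5 residual degrees of freedom and 1.85 prior ones. The single ESC array adds nothing to the estimate of the spread, so both ESC comparisons assume that ESC arrays would vary like the iPSC arrays. A probe not above background on every array of a group has only a bound there. Its fold is given as "at least", computed from the mean of the brighter group against the mean, over the dimmer arrays, of the higher of the probe's own signal and the lowest signal well above background on that array. The test was run on simulated data for OSKH against OSK with 22685 features, of which 200 were changed. It recovered 61% of the genes changed 2-fold and 80% of those changed 4-fold, with 7 false calls among 148. The simulated noise was normal and independent for each gene at the fitted spread. It held no correlation between genes, slide row effect or outlying array, so these rates may not hold for the real arrays.

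A set of 24 gene lists (520 genes, of which 447 were tested) was tested with camera at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. A list needed at least 5 tested members. The lists cover pluripotency, the 2-cell-like state, imprinting, the germline, embryonic and extraembryonic lineages, fibroblasts and feeders, blood and endothelium, telomeres, p53, linker histones, chromatin, interferon, sex chromosomes, hypoxia, amino acid and unfolded protein stress, cholesterol, the cell cycle, LIF, Wnt with FGF and TGF-beta, and extracellular matrix. Distance to ESC was the root mean square log2 difference of an array to the ESC array over all features. Spread within a group was the same distance to the mean of the other arrays of the group, scaled for group size. Both were tested with an exact two-sided permutation test over 35 splits, whose smallest possible p is 0.0286.

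Genes were named by a fixed rule. The rule takes up to 12 rises and 12 falls past the threshold for OSKH against OSK, filled up to 8 per direction by the smallest unadjusted p, up to 8 per direction past the threshold against ESC, 2 members of each list with the smallest p where none passed (4 where some did), and H1foo, Pou5f1, Sox2, Klf4, Nanog and Xist. A gene that this rule takes is not reported here. The lists, tests, naming rule and the alternatives listed next were chosen before the data were examined, except the list tests against ESC, added afterwards. The alternatives were normexp background correction with offset 50, quantile normalization, median centring, a percentile over probes detected on all arrays, no filter or a stricter filter on dim probes, the mean of all probes of a gene, the deposited value table, another variance model, stricter thresholds, other distances, other set tests, fits without ESC, with a replicate block or with slide row as a block, and each iPSC array left out in turn. A mean signal per spot was not used here, so normexp was run on the median signal and median background of each spot.

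Whether equal array numbers pair the iPSC samples was checked from deviations from the group means over all features. The correlations of OSKH 1 with OSK 1, OSKH 2 with OSK 2 and OSKH 3 with OSK 3 were 0.49, 0.21 and 0.37, all above 0.1, so the numbers were taken to pair the samples. Arrays of unequal number ran from -0.40 to 0.16, and OSKH 4 with OSK 3 (0.16) was also above 0.1, so the check is weak. The main tests leave the pairing out. It enters among the alternatives as the replicate block, fitted on OSKH 1 to 3 and OSK 1 to 3 alone. That fit leaves out OSKH 4 and ESC, so its mean differences equal those without OSKH 4. The pairing comes from this check and from the shared slide column, and the labels name no shared culture or day. Figures were drawn with matplotlib.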

Results

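Gene expression was measured in undifferentiated mouse pluripotent cells on 8 one-colour arrays. There were 4 arrays of OSKH iPSCs, 3 arrays of OSK iPSCs, which the series names as the control group, and 1 array of an ESC line of the C57BL/6J strain. OSK is taken to stand for Oct4, Sox2 and Klf4, the transcription factors used to reprogram somatic cells, and the H for H1foo, the linker histone of the oocyte. The labels do not spell these names out. The comparisons ask whether iPSCs made with and without the additional factor differ, and how each kind relates to ESCs. Levels are log2 signals relative to the 75th percentile of the array, and differences are in log2 units with standard errors (SE) from limma, unless stated otherwise. Between 51.4% and 59.0% of probes were well above background on each array. Xist, the RNA that coats the inactive X chromosome, was not well above background on any array, and the Y-linked Ddx3y (1.19 to 1.71) and Eif2s3y (2.88 to 3.63) were measured on all 8.

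No gene passed the test between OSKH and OSK, and those with the smallest p in each direction are given here. Slc40a1, the iron exporter ferroportin, lay 2.49-fold higher in OSKH (log2 difference 1.32, SE 0.14). Uba7, the activating enzyme for the ubiquitin-like protein Isg15, differed by 1.32 (SE 0.14), and Herc6, a ligase of the same pathway, by 1.06 (SE 0.15), each measured on 1 of 3 OSK arrays. Bend6, measured on 2 of 3 OSK arrays, differed by 0.82. Mogat1, Iqgap2, H2bc23 (measured on 3 of 4 OSKH arrays) and Il10rb were not well above background on any OSK array and were at least 1.66-fold, 1.44-fold, 1.52-fold and 1.58-fold higher in OSKH. These values depend on the background correction: with normexp the log2 differences were 0.42 for Uba7, 0.33 for Herc6, 0.29 for Bend6, 0.18 for Mogat1, 0.22 for Iqgap2, 0.27 for H2bc23 and 0.27 for Il10rb, which for the last 4 genes is below the bounds given. On the other side, Cdkn2a, which encodes the p16 and p19 inhibitors of the cell cycle and of Mdm2, lay lower in OSKH by -0.85 (SE 0.13), at 0.24 ± 0.21 (SD, n = 4) against 1.09 ± 0.12 (SD, n = 3). Themis2, measured on 3 of 4 OSKH arrays, differed by -1.46, Aoc1, a diamine oxidase, by -1.02, Slc47a2 by -0.78, Fitm2 by -0.52, Zim3 by -0.43 and Wrap73 by -0.37. With normexp, Themis2 was at -0.66, Aoc1 at -0.51 and Zim3 at -0.25. Limma called 0 of 22685 features at an adjusted p under 0.05, and the smallest adjusted p was 0.463. At an unadjusted p under 0.05 there were 1470 features, 724 higher and 746 lower in OSKH, where chance alone gives 1134. Groups did not overlap in 1665 features (7.34%), against 5.71% by chance. With slide row as a block, the comparison rests on OSKH 4 against the 3 OSK arrays of the same row, and 47 features were called.

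**Figure D1:**
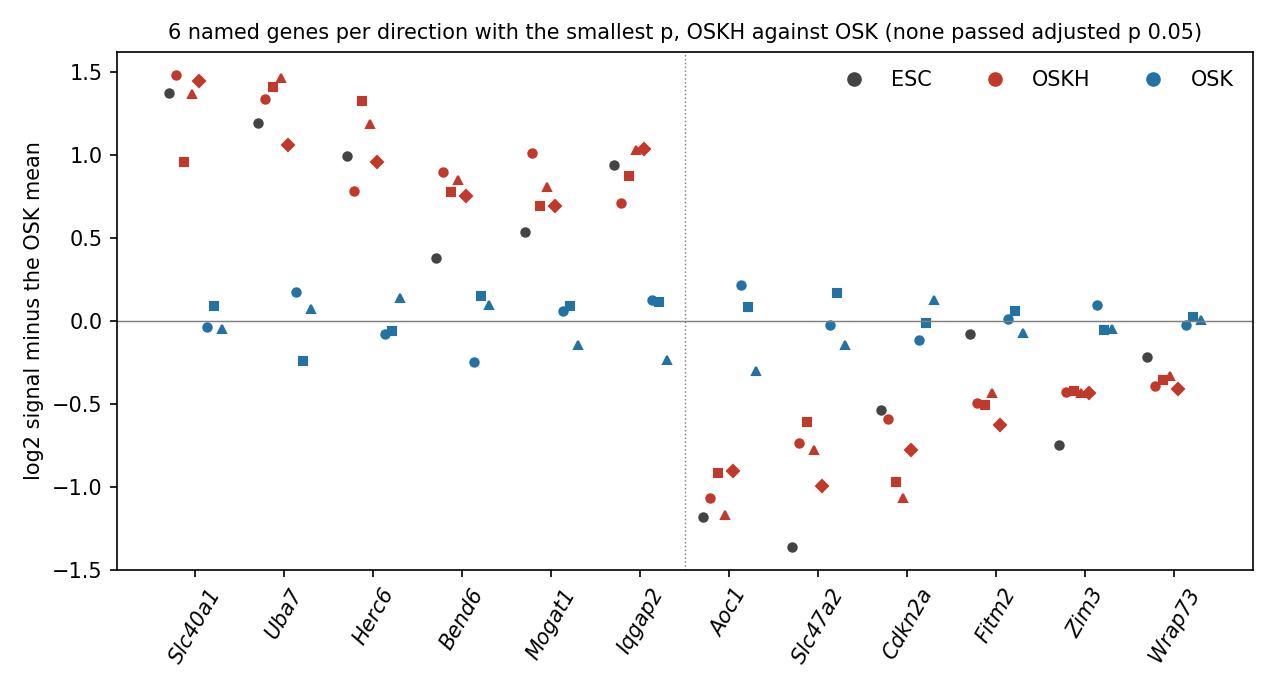
Each point is one array's log2 signal for a gene minus the mean of the 3 OSK arrays; colours mark ESC, OSKH and OSK, and circle, square, triangle and diamond mark arrays 1 to 4. The 6 named genes with the smallest p in each direction are drawn, none passed the adjusted threshold, and Slc40a1 lies 1.32 above and Aoc1 -1.02 below the OSK mean on average in OSKH.

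The reprogramming factors did not separate the groups. H1f8, the current symbol of H1foo, was at -1.34 ± 0.24 (SD, n = 4) in OSKH and -1.51 ± 0.18 (SD, n = 3) in OSK, with the ESC array at -1.35. The difference of 0.17 (SE 0.16) had a limma adjusted p of 0.909, and was 0.091 without OSK 2, 0.11 without OSKH 3, 0.27 without OSK 1 and 0.29 without OSKH 2. Pou5f1, which encodes Oct4, differed by 0.01 (SE 0.08), Sox2 by 0.10 (SE 0.17) and Klf4 by 0.11 (SE 0.46). Nanog, another core pluripotency factor, lay 0.54 (SE 0.21) higher in OSKH, with a limma adjusted p of 0.752, and by 0.21 with the mean of its probes. Where the probes lie in each transcript was not examined, so a transgene without the native untranslated regions may or may not be seen by them. The differences of Pou5f1, Sox2 and Klf4 changed sign when single arrays were left out: without OSKH 1 they were -0.0043, -0.036 and -0.28.

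Of the 24 gene lists, 4 were higher in OSKH than in OSK by camera. Interferon and innate immunity genes had the lowest adjusted p (1.3e-09, and adjusted p = 0.427 with an estimated correlation), with 27 of 27 measured members higher and a mean difference of 0.68. B2m, the light chain of class I histocompatibility molecules, differed by 0.63 (SE 0.10), and Ifit3, an interferon-induced antiviral protein measured on 1 of 3 OSK arrays, by 0.88 (SE 0.26). The hypoxia and glycolysis list was higher on average by 0.33 (adjusted p = 6.1e-04, and adjusted p = 0.658 with an estimated correlation), with 21 of 27 members higher. Pfkfb3, a regulator of glycolysis, differed by 0.49, while Hk2, a hexokinase, lay at -0.34. Of linker histones, 8 of 8 were higher, on average by 0.34 (adjusted p = 6.1e-04, and adjusted p = 0.427 with an estimated correlation). H1f0, the replacement linker histone of non-dividing cells, measured on 1 of 3 OSK arrays, differed by 0.97 (SE 0.27) and H1f6, a testis form, by 0.47 (SE 0.17). Trophectoderm genes were higher by 0.45 (adjusted p = 0.035, and adjusted p = 0.738 with an estimated correlation), with 13 of 15 members higher, among them Krt7, a keratin, at 1.01 (SE 0.40), while Fgfr2 lay at -0.20. With normexp, Ifit3 differed by 0.34, H1f0 by 0.38 and Krt7 by 0.62. Krt7 was at 0.64 without OSKH 4 and Fgfr2 at -0.13 without OSKH 2. By limma, 0 members of these lists passed over all genes, and adjusted over the list alone 1 interferon gene, B2m, and 0 genes of the other 3 lists did. With an estimated correlation between genes, none of the 4 calls held. That test called 0 lists in each of the 35 ways to split the 7 iPSC arrays into 4 and 3. Among these was a split with 3865 features at an unadjusted p under 0.05. Its power may be low here, so a lost call does not show that a list is unchanged. The mean of the interferon list followed slide row. It was 0.69, 1.09 and 1.27 on OSKH 1 to 3 and 1.05 on ESC, all in row 1, and 0.14 on OSKH 4 and 0.26, -0.14 and 0.22 on OSK 1 to 3, all in row 2. Single members did not all do so, and 13 of 27 lay above the OSK mean on OSKH 4. B2m was at 2.09 on OSKH 4 against 1.31 to 1.39 on the OSK arrays. It was named for its small p between the groups, which favours a gene that is high on OSKH 4. With slide row as a block, the differences were 0.03 for interferon (adjusted p = 0.631) and 0.15 for hypoxia (adjusted p = 0.561), which ended both calls, 0.42 for linker histones (adjusted p = 0.011) and 1.38 for trophectoderm (adjusted p = 1.1e-06). With row as a block and an estimated correlation, the adjusted p was 0.467 for linker histones and 0.188 for trophectoderm. The hypoxia difference was 0.19 without OSKH 3. The trophectoderm call ended with array number as a block (0.14, adjusted p = 0.133), a fit that also leaves out OSKH 4. It ended without OSKH 1 (0.40), OSKH 4 (0.14) or OSK 3 (0.37) and with probes well above background on all arrays (adjusted p = 0.053). The trophectoderm difference was 0.70 without OSKH 2. With OSKH 2 and 3 as the only OSKH arrays, linker histones did not pass (0.23, adjusted p = 0.146) and interferon genes differed by 1.06. Over all alternatives the adjusted p ran from 5.3e-19 to 0.908 for interferon, 6.6e-05 to 0.908 for hypoxia, 6.4e-05 to 0.694 for linker histones and 1.1e-06 to 0.958 for trophectoderm.

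A further 3 lists were lower in OSKH than in OSK by camera. The 2-cell-like list holds genes of the zygotic activation stage that a small part of cultured ESCs express at any time. Of its 21 genes, 9 passed the filter, which the 3 OSK arrays alone could meet. All 9 lay lower in OSKH, on average by -1.38 (adjusted p = 8.8e-05, and adjusted p = 0.427 with an estimated correlation). By array the list means overlapped, with OSKH 2 at 0.66 and OSK 3 at 0.21. An exact two-sided permutation test of the list means gave p = 0.0857 (adjusted p = 0.549 over the lists). Tcstv1, measured on 1 of 4 OSKH arrays, differed by -2.58 (SE 0.79) and Usp17la by -1.34 (SE 0.43). Members of these families are near-identical copies whose probes may not be specific. The p53 target and apoptosis list differed by -0.17 (adjusted p = 0.0033, and adjusted p = 0.427 with an estimated correlation), with 17 of 24 members lower. Bbc3, the death-promoting protein Puma, lay at -0.41 (SE 0.10) and Mdm2, the ligase that degrades p53, at -0.47 (SE 0.16). Germline genes differed by -0.24 (adjusted p = 0.046, and adjusted p = 0.738 with an estimated correlation), with 17 of 21 members lower. Stra8, a gene of meiotic entry, lay at -1.63 (SE 0.42) and Dazl, an RNA-binding protein of germ cells, at -0.78 (SE 0.21). With normexp, Tcstv1 differed by -0.66, Usp17la by -0.86 and Dazl by -0.37. By limma, 0 members of the 3 lists passed over all genes or adjusted over the list alone. None of the 3 calls held with an estimated correlation. With slide row as a block, the 2-cell-like list differed by -1.65 (adjusted p = 0.026) and germline genes by -0.46 (adjusted p = 0.0050), and the p53 call ended (-0.065, adjusted p = 0.373). With row as a block and an estimated correlation, the adjusted p was 0.536 for the 2-cell-like list and 0.3985 for germline genes. The 2-cell-like difference was -0.72 with normexp background correction and -0.95 without the filter on dim probes. It was -0.88 with probes well above background on all arrays and -0.91 with OSKH 2 and 3 as the only OSKH arrays. The p53 difference was -0.094 without OSKH 1. The germline call ended with array number as a block (-0.16, adjusted p = 0.103), a fit that also leaves out OSKH 4. It ended with normexp (-0.17, adjusted p = 0.056) and without the filter on dim probes (-0.20, adjusted p = 0.097). It also ended with probes well above background on all arrays (-0.23, adjusted p = 0.054). Leaving out OSKH 2 (-0.25), OSKH 3 (-0.21), OSKH 4 (-0.16), OSK 1 (-0.21) or OSK 2 (-0.15) ended it too. The germline difference was -0.36 without OSK 3. Over all alternatives the adjusted p ran from 9.4e-07 to 0.694 for the 2-cell-like list, 0.0011 to 0.805 for p53 and 0.0022 to 0.863 for germline genes. Of all 35 ways to split the 7 iPSC arrays into 4 and 3, 22 gave at least the 7 called lists of the real groups.

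**Figure D2:**
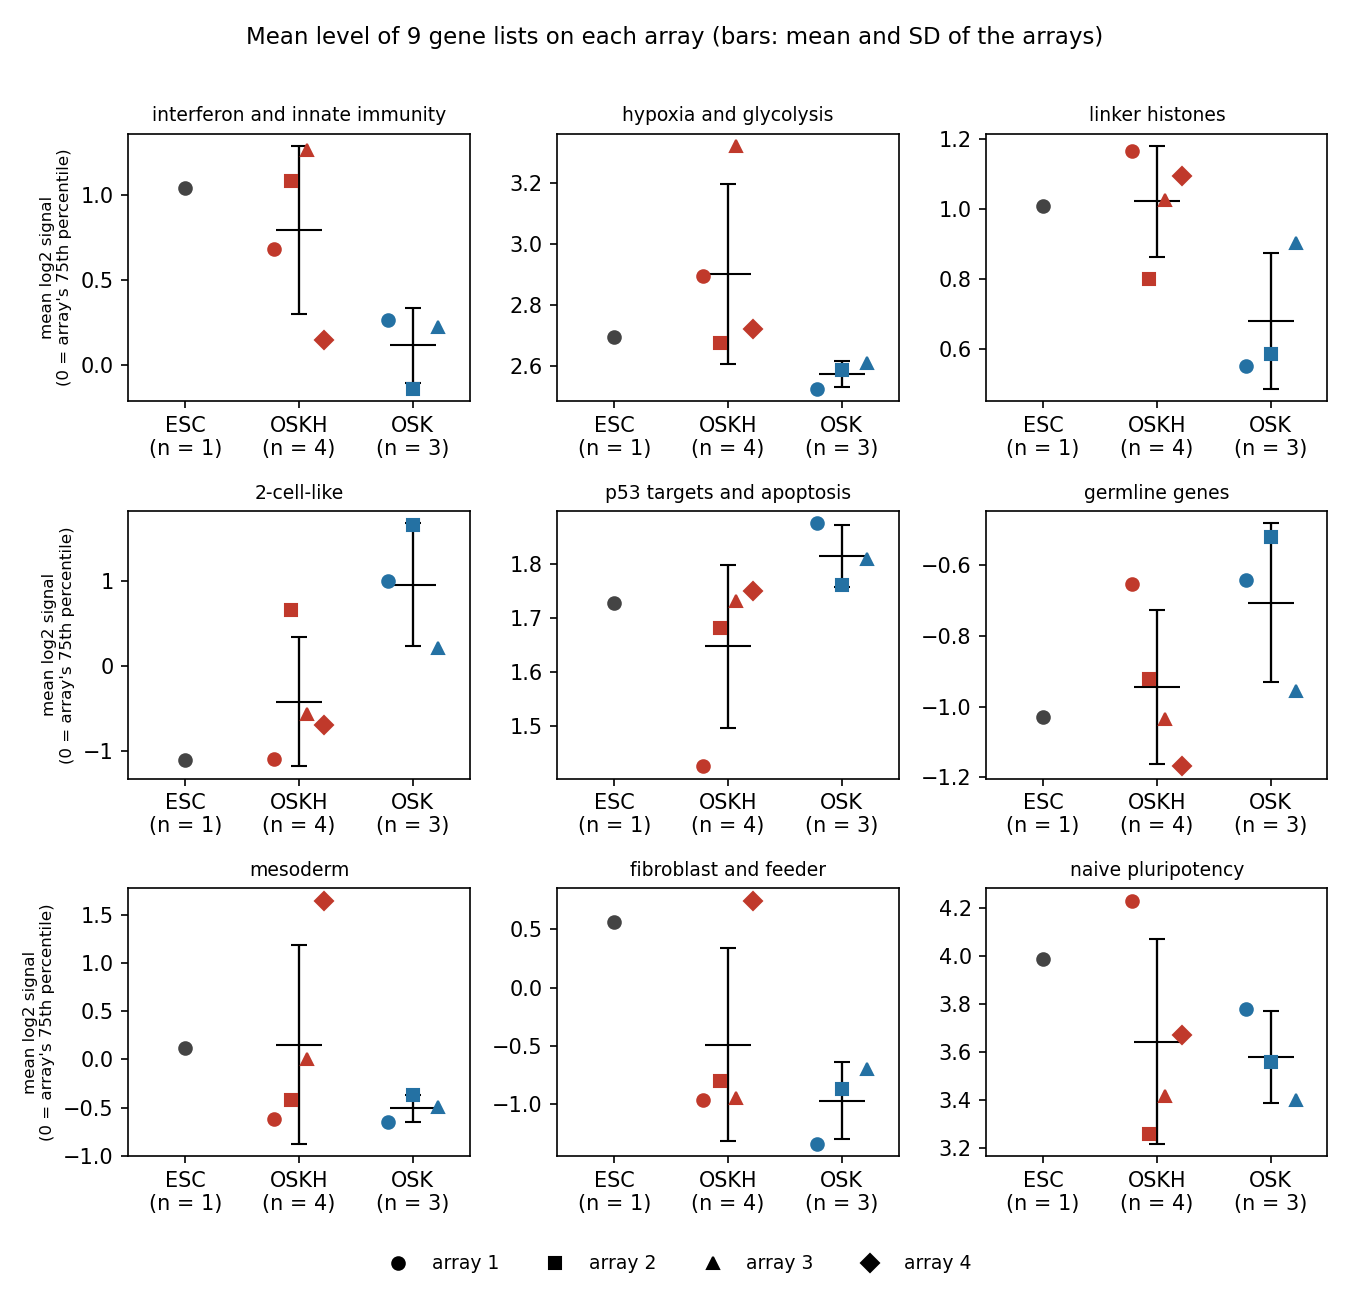
Each point is the mean log2 signal of one gene list on one array, relative to that array's 75th percentile; bars give the mean and SD of the 4 OSKH and 3 OSK arrays, the ESC array has no replicate, and each panel has its own vertical scale. For interferon genes OSKH 4 (0.14) lies among the OSK arrays, and for mesoderm genes OSKH 4 (1.65) lies above the 7 other arrays.

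The other 17 lists did not pass, and the smallest adjusted p among them was 0.088. Naive pluripotency genes differed by 0.064 on average, with 19 of 28 members higher, and Gbx2 lay at -1.53 (SE 0.47). Primed and formative genes differed by 0.32 (Fst 1.84, Otx2 1.49), LIF and STAT3 response genes by -0.028 (Id3 1.00, Myc -0.57) and the Wnt, FGF and TGF-beta list by 0.17 (Dusp4 0.76, Ccn1 0.60). Among lineage lists, mesoderm differed by 0.66 (Eomes 1.95, Snai1 0.91), primitive and definitive endoderm by 0.44 (Foxa2, measured on 2 of 3 OSK arrays, 3.08 with SE 1.64, Sparc -0.33), ectoderm and neural genes by -0.23 (Neurod1 -1.24, Olig2 -0.70) and haematopoietic and endothelial genes by 0.22 (Gata1 0.69, Runx1 0.50). Fibroblast and feeder genes differed by 0.48. Postn, a matrix protein of fibroblasts, was not well above background on any OSK array and was at least 1.41-fold higher in OSKH, where 2 of 4 arrays measured it, while Vim lay at -0.51. The bound for Postn rests largely on OSKH 4 (-1.91), with OSKH 1 to 3 at -4.24, -3.70 and -6.08. The extracellular matrix list differed by 0.10 (Cldn7 0.64). Imprinted genes differed by 0.12 (H19 1.17, Phlda2 -0.47), chromatin regulators by -0.043 (Hdac2 0.27, Mbd3 -0.13), telomere genes by 0.0058 (Pot1b 0.16, Smarcal1 0.12) and sex chromosome genes by 0.023 (Kdm5c -0.15, Kdm6a 0.17). Amino acid and unfolded protein stress genes differed by 0.23 (Vldlr 1.14, Hsp90b1 0.19) and cholesterol synthesis genes by -0.031 (Hmgcs1 -0.29, Srebf2 -0.19). Cell cycle genes had a mean of -0.014 and a median of 0.016, with Cdkn2b at -0.65. By limma, 0 genes of these lists passed over all genes, and adjusted over the list alone 1 did, Cdkn2a of the cell cycle list. Lists passed camera when single arrays were left out: without OSKH 1, mesoderm at 0.92, primed and formative genes at 0.52, fibroblast genes at 0.64, imprinted genes at 0.18 and chromatin regulators at -0.092. Without OSKH 4, ectoderm genes passed at -0.39 and stress genes at 0.32, without OSKH 3 fibroblast genes at 0.63, and without OSK 3 primed and formative genes at 0.55. With an estimated correlation none of these lists passed without those arrays, and their adjusted p ran from 0.509 (mesoderm without OSKH 1) to 0.752 (fibroblast genes without OSKH 1). Ectoderm genes also passed with array number as a block, again without OSKH 4 (-0.39, adjusted p = 0.020, and adjusted p = 0.690 with an estimated correlation). Over all alternatives their adjusted p ran from 0.020 to 0.978. The ectoderm difference was 0.25 with slide row as a block. Other differences shrank: without OSKH 4, mesoderm was at 0.16, endoderm at 0.090, fibroblast genes at 0.066, the Wnt, FGF and TGF-beta list at 0.057, the extracellular matrix list at 0.015, imprinted genes at 0.074 and chromatin regulators at -0.0089. Without OSKH 1, stress genes were at 0.065, ectoderm genes at -0.033 and haematopoietic genes at -0.0016, and without OSK 1 primed and formative genes were at 0.16. Among the genes named here, Foxa2 was at 1.52, Eomes at 1.04, Gata1 at 0.40 and Ccn1 at 0.29 without OSKH 4, and Dusp4 at 0.47, Cdkn2b at -0.42, Hmgcs1 at -0.17 and Kdm6a at 0.054 without OSKH 1. Runx1 was at 0.25, Smarcal1 at 0.069, Pot1b at 0.052 and Kdm6a at 0.26 without OSK 1, and Kdm6a at 0.078 without OSK 2. Gata1 was at 1.03 without OSKH 2, and Runx1 at 0.76 without OSKH 1 and 0.79 without OSK 3. Over all alternatives, Neurod1 ran from -2.035 to -0.74 and Olig2 from -0.84 to -0.30.

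Within slide row 2, where OSKH 4 is the only OSKH array, limma called 47 features against OSK 1 to 3 at an adjusted p under 0.05, 38 higher and 9 lower. This test assumes that a group of OSKH 4 would vary like the other iPSC arrays. Of the 47, 39 had a gene name. Foxa2, a transcription factor of the endoderm and node measured on 2 of 3 OSK arrays, was higher by 7.75 (limma adjusted p = 0.041, with a range of 0.041 to 0.9999 over all alternatives), Gsc, a gene of the organiser measured on 1 of 3 OSK arrays, by 7.32 (limma adjusted p = 0.019), Sp5, a Wnt target, by 5.66 and Lhx1, a gene of the anterior mesendoderm, by 3.74. OSKH 1 to 3 differed from OSK in these 4 genes by 1.52, 0.40, -0.039 and -0.39, and the ESC array by 4.53, 3.00, 1.83 and 0.20. Krt8, a keratin of simple epithelia, was higher by 3.59, Tuba8, a tubulin, by 3.30 and Foxj1, a transcription factor of ciliated cells, by 3.08, while Insm1, a transcription factor of neuroendocrine cells, differed by -2.09. Apart from Foxa2, the genes of this paragraph were chosen after their values were seen. The matrix genes Col1a1 (3.07) and Thbs1 (3.77, measured on 1 of 3 OSK arrays) were also among the 47, with the ESC array at 2.69 and 3.47. With slide row as a block, the mesoderm list differed by 2.16, fibroblast genes by 1.72, endoderm genes by 1.495, primed and formative genes by 0.61, the Wnt, FGF and TGF-beta list by 0.51 and imprinted genes by 0.26, and camera called all 6 at its preset correlation. With an estimated correlation none of the 6 passed, and the adjusted p was 0.188 for mesoderm, fibroblast and endoderm genes, 0.740 for primed and formative genes, 0.240 for the Wnt, FGF and TGF-beta list and 0.247 for imprinted genes.

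Against the ESC array, naive pluripotency genes were lower in OSKH by -0.35 on average, with 27 of 28 members lower (camera adjusted p = 0.011, and adjusted p = 0.972 with an estimated correlation). The mean of the list was 3.26, 3.42 and 3.67 on OSKH 2 to 4 and 3.99 on ESC, while OSKH 1 (4.23) lay above ESC. Klf4 lay at 2.51 ± 0.88 (SD, n = 4) against 3.52 on the ESC array. Cell cycle genes differed by -0.23, with 22 of 24 members lower (adjusted p = 0.0012, and adjusted p = 0.864 with an estimated correlation). Fibroblast and feeder genes differed by -1.06, with 20 of 23 lower (adjusted p = 0.0012, and adjusted p = 0.972 with an estimated correlation). Their mean was -0.96, -0.80 and -0.95 on OSKH 1 to 3 and 0.57 on ESC, while OSKH 4 (0.75) lay above ESC. Postn, measured on 2 of 4 OSKH arrays, lay at -3.98 ± 1.71 (SD, n = 4) against -1.06 on ESC. Amino acid and unfolded protein stress genes were higher by 0.38, with 16 of 19 members higher (adjusted p = 0.010, and adjusted p = 0.629 with an estimated correlation). The other 20 lists did not pass. Testing the lists against ESC was decided after the data were seen. By limma, 0 list members passed over all genes or adjusted over the list alone. The cholesterol, matrix, imprinted and endoderm lists had negative means and a positive direction in camera. Camera compares t-statistics, in which each difference is divided by its error, of a list with those of all other genes, and not log2 means. Limma called 0 features (smallest adjusted p 0.392), and 990 had an unadjusted p under 0.05, fewer than the 1134 that chance gives. With 1 ESC array, this assumes that ESC arrays vary like iPSC arrays. The naive call ended without OSKH 2 (-0.22) or OSKH 3 (-0.27), and without OSKH 1 the naive difference was -0.54, the stress difference 0.21, and 8 lists passed. Gained calls were chromatin (-0.15), haematopoietic (-0.55), LIF (-0.53) and mesoderm genes (0.29) without OSKH 1, hypoxia (0.27) and LIF genes (-0.42) without OSKH 4 and hypoxia genes (0.28) without OSKH 2. With an estimated correlation none of the lists passed without those arrays, and the smallest adjusted p was 0.680 for these gained calls. Without the filter on dim probes 11 features were called, 10 of them lower in OSKH. The filter removes all 11, and the 10, such as Olfr26, an olfactory receptor gene, were not well above background on any OSKH array.

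Against the same ESC array, OSK iPSCs had lower interferon and innate immunity genes, by -0.93 on average with 25 of 27 members lower (camera adjusted p = 3.4e-05, and adjusted p = 0.620 with an estimated correlation). B2m was at 1.35 ± 0.04 (SD, n = 3) against 2.26 on ESC. All OSK arrays lie in slide row 2 and the ESC array in row 1, so slide row and group cannot be told apart here. Fibroblast and feeder genes differed by -1.54 (adjusted p = 1.2e-04), naive pluripotency genes by -0.41 (adjusted p = 0.0091) and cell cycle genes by -0.21 (adjusted p = 0.017). With an estimated correlation the adjusted p was 0.620, 0.644 and 0.620 for these 3 lists. The 2-cell-like list passed with a mean difference of 2.07 (adjusted p = 0.022), and germline genes were higher by 0.32 (adjusted p = 0.017). Both had an adjusted p of 0.620 with an estimated correlation. Of the 9 2-cell-like members, Tcstv1, Tmem92 and Usp17lb were not well above background on ESC, and of the other 6, 3 lay higher and 3 lower, with a mean difference of 1.39. Over the 18 of 21 germline members measured on ESC the mean difference was 0.32. The other 18 lists did not pass, and these list tests too were decided after the data were seen. By limma, 0 list members passed over all genes, and adjusted over the list alone 2 interferon genes did. The cholesterol and mesoderm lists had negative means and a positive direction in camera. Limma called 0 features (smallest adjusted p 0.207) under the same assumption on the ESC array, and 1365 had an unadjusted p under 0.05. The 2-cell-like (1.72) and germline calls (0.23) ended without OSK 2 and the naive call (-0.32) without OSK 3. Linker histones (-0.44) and primed genes (-0.66) passed without OSK 3, and LIF genes (-0.43) without OSK 1. Leaving out OSKH arrays, which changes only the spread here, gave calls for LIF, haematopoietic and p53 genes (OSKH 1), linker histones (OSKH 2) and trophectoderm genes (OSKH 4). The smallest adjusted p of these gained calls was 0.585 with an estimated correlation. In addition, 9 features were called without the filter on dim probes.

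The 2 kinds of iPSC lay at similar distances from the ESC array. The root mean square log2 difference over 22685 features was 0.473 ± 0.038 (SD, n = 4) for OSKH and 0.498 ± 0.041 (SD, n = 3) for OSK (exact two-sided permutation test, p = 0.486). Pearson's r with ESC, across genes that are not independent replicates, was 0.990 ± 0.0017 (SD, n = 4) and 0.989 ± 0.0018 (SD, n = 3). The farthest arrays were OSKH 1 (0.529) and OSK 2 (0.527), and the nearest was OSK 3 (0.450). Within slide row 2, OSKH 4 minus the OSK mean was -0.043, which no test could decide with 1 OSKH array there, and row 1 holds no OSK array. The OSKH arrays lay 0.390 ± 0.093 (SD, n = 4) from the mean of their own group and the OSK arrays 0.282 ± 0.025 (SD, n = 3), a difference of 0.107 (exact two-sided permutation test, p = 0.143) that was 0.046 without OSKH 1. Since no gene was called between OSKH and OSK, the genes at an unadjusted p under 0.05 were compared with ESC, which was decided after the data were seen. Of these 1470 features, 67.8% lay nearer the ESC value in OSKH than in OSK. The ESC array shared slide row 1 with OSKH 1 to 3 and a column with OSKH 4, while all OSK arrays lay in row 2 and in other columns. An effect of slide position could raise this share, and it cannot be told apart from the groups here. The share was 55.3% without OSKH 1 and 75.9% without OSK 3, and 6 of 35 splits of the 7 arrays gave a share at least as high.

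**Figure D3:**
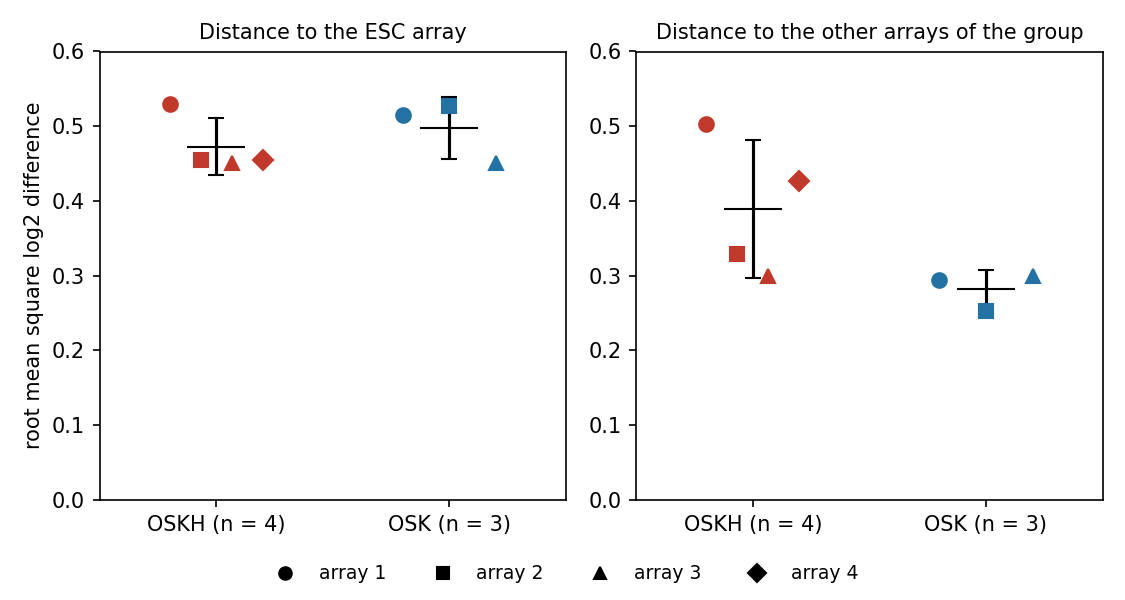
Each point is one iPSC array's root mean square log2 difference over 22685 features, to the ESC array on the left and to the mean of the other arrays of its group, scaled for group size, on the right; bars give mean and SD, and marker shape gives the array number. Distances to ESC overlap between OSKH (0.473) and OSK (0.498), and OSKH 1 (0.503) lies farthest from its own group.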

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

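The counts over splits of the arrays, slide row as a block, the estimated correlation and the other corrections and scalings had been planned. Their use as tests of an explanation, the list means and medians compared between single arrays, the differences by array number and the 2-cell-like mean as 1 feature were chosen only after the result was seen. Among 92 results tested in the 4 OSKH arrays, 4 had 1 array far from the other 3, where chance gives about 1 in 20, or 4.6. The fibroblast and feeder list was at 0.75 on OSKH 4 against a mean of -0.90 on the other 3. OSKH 1 lay 0.5295 from the ESC array against 0.4536 for the other 3. Snai1, a repressor of epithelial genes, was at 0.77 on OSKH 1 against -0.25. Fgfr2 was at -1.62 on OSKH 2 against -1.35.

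Interferon genes were higher in OSKH 1 to 3 than in OSK by 0.90 on average (27 of 27 members), and on the ESC array by 0.93 (25 of 27), but not on OSKH 4, which differed from OSK by 0.03063 (13 of 27 higher) and lay inside the OSK range. By camera at its preset correlation, the list kept an adjusted p of at most 4.0e-09 under 5 other corrections and scalings. In the main fit the adjusted p was 0.427 with an estimated correlation. The deposited value table, median centring and the percentile of detected probes only shift whole arrays, which moves all genes of an array alike. Such shifts changed some list calls against ESC, but they test this explanation only weakly. Normexp and quantile normalization can move a list against other genes, and both kept the call. To that extent, background correction or scaling as the whole cause is argued against. Fibroblast or feeder cells are argued against, since their list had a median difference of -0.034 between OSKH 1 to 3 and OSK (mean 0.066), against 0.63 for interferon genes. The values needed for an effect of slide row, or of work done in that order, are there over the list. Such an effect may account for most of the difference, though within row 2 this rests on OSKH 4 as the only OSKH array. B2m was high there too (2.09), but it was picked by its small p between the groups, so it weighs little. A difference brought by the additional factor stays open and untested, with OSKH 4 as an exception to it.

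Mesoderm genes lay 2.00 higher on OSKH 4 than on OSKH 1 to 3 (13 of 16 members). Medians over the list were tried first and decided nothing, with an excess of 0.77 (SE 0.76) on OSKH 4, 0.083 (SE 0.15) for OSK, and OSKH 4 above ESC by 0.94 (SE 0.48) for mesoderm and 0.15 (SE 0.16) for fibroblast genes, and means were chosen after these were seen, so what follows rests on a few strongly raised members. All SEs in this paragraph are over the members of a list, which are not independent, and do not measure the spread between samples. By means, slide row is argued against over this list, unless OSK and OSKH differ there in the other direction. The OSK arrays of the same row were at -0.65, -0.37 and -0.50, against 1.65 on OSKH 4, and differed from OSKH 1 to 3 by -0.16 (SE 0.12). Scaling as the whole cause is argued against, since the excess was at least 1.499 under 5 other corrections and scalings. Of these, normexp and quantile normalization carry the point, since the others only shift whole arrays. Fibroblast or feeder cells stay open. By means, OSKH 4 exceeded ESC over the mesoderm list by 1.35 more than over the fibroblast list (SE 0.40). This sets 1 array against 1, rests on a few members and assumes that both hold the same kind of feeder. No group in the design sets OSKH 4 apart, so no biological explanation was tested, and partial differentiation of that culture stays an untested candidate.

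The 2-cell-like list was lower in OSKH by -1.38, and the differences between arrays of equal number were -2.10, -0.998 and -0.776 for OSKH 1 to 3 against OSK 1 to 3. By camera at its preset correlation, the adjusted p was at most 1.8e-04 under 5 other corrections and scalings. Of these, normexp and quantile normalization bear on this most, since the others only shift whole arrays. Both kept the call, which argues against scaling as the whole cause, although the difference was -0.72 with normexp. Slide row stays open: the difference was -1.65 with row as a block, which rests on OSKH 4 as the only OSKH array in the row of the OSK arrays. Members that move together may have been counted as separate evidence: the adjusted p was 0.4266 with an estimated correlation (9.4e-07 to 0.694 over all alternatives), and the mean of the members, tested as 1 feature by limma, had an unadjusted p of 0.0268 (0.0138 with the replicate block), and an adjusted p over all features of 0.7504 (0.426). Whether the additional factor plays a part stays open.

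Chance could not be excluded for 3 results between OSKH and OSK. Of the 35 splits of the 7 arrays into 4 and 3, 7 gave at least the 1470 features at an unadjusted p under 0.05 (highest other 3865), 22 gave at least 7 called lists (highest other 11), and 6 gave a share nearer ESC of at least 67.8% (highest other 77.8%). For the 0 calls at an adjusted p under 0.05 the count of splits says nothing, since all 35 must give at least 0 (highest other split 22). The split with 3865 features, far above the real count, set OSKH 1, OSK 1 and OSK 2 against the other 4 arrays and points to a structure of the samples other than the groups. Of the 8 splits that part all 3 pairs of equal array number, which is too few for a share under 0.05, the real one gave 1470 features and the highest other 1007, and for lists 7 against 9.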

How the results depend on the processing

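The fit of OSKH 2 and OSKH 3 alone, the lists against ESC, the ESC share at unadjusted p, the 2-cell-like members as 1 value, and an estimated correlation combined with another alternative were chosen after seeing the data, and the causes of the changes below were not tested unless stated. OSKH against OSK gave 0 calls in limma under all alternatives, with 1470 features at an unadjusted p under 0.05, except slide row as a block and within slide row 2, which are the same estimate and gave 47 each, because OSKH 4 alone then stands for OSKH. Against ESC, the only calls came without the filter on dim probes, 11 for OSKH and 9 for OSK, all of them features the filter removes. None of the 4 reprogramming factors was called anywhere. The 7 lists called became 11 without the filter, 0 with an estimated correlation and 0 by fry, and 6 to 11 when single arrays were left out. The 4 lists of OSKH against ESC became 0 with an estimated correlation, 0 by fry and 3 to 8 without single arrays. The 6 of OSK against ESC became 10 with the percentile of detected probes, 0 with an estimated correlation, 0 by fry and 4 to 9 without single arrays. With OSKH 2 and 3 as the only OSKH arrays 10 lists were called, 5 in each direction. With an estimated correlation, 0 lists of OSKH against OSK passed with slide row as a block, the replicate block, no filter, the percentile of detected probes, OSKH 2 and 3 alone or any single array left out, and against ESC 0 with no filter, that percentile or any single array left out. With the replicate block, which leaves out OSKH 4 and ESC, 0 genes and 6 lists were called. Apart from the germline, trophectoderm and ectoderm lists it changed no call. These lists changed in the same way without OSKH 4 and with no block. The share nearer ESC ran from 55.3% to 75.9% without single arrays. The distance difference of -0.025 turned to 0.00064 with normexp and 0.0040 with probes well above background on all arrays. With single arrays left out it ran from -0.048 (without OSK 3) to -0.010 (without OSK 2). The spread difference kept its direction and missed the threshold throughout. No share of called genes nearer ESC was computed, since 0 genes were called.

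Single values turned direction, all of them without a call unless stated. With slide row as a block or within row 2, Pou5f1 was -0.089 and Sox2 -0.088. With row as a block, the ectoderm list was 0.25, LIF 0.085, sex chromosome -0.15 and telomere -0.080. With normexp, Pou5f1 was -0.032. Without the filter, LIF was -0.028 with its test in the other direction and sex chromosome -0.053. With the mean of all probes, sex chromosome was -0.019, and fry turned its direction at 0.023. With the replicate block, camera turned the direction of the cell cycle list at -0.029. With OSKH 2 and OSKH 3 alone, Sox2 was -0.0094, Klf4 -0.54, haematopoietic genes -0.045 and trophectoderm -0.093, and cholesterol genes at 0.16 and naive genes at -0.24 were called. Without single arrays, Pou5f1 ran from -0.016 to 0.045, Sox2 from -0.036 to 0.20, Klf4 from -0.28 to 0.38, and the lists ran for fibroblasts from 0.066 (camera's direction turned) to 0.64, cholesterol from -0.10 to 0.088, haematopoietic genes from -0.0016 to 0.34, the cell cycle from -0.058 to 0.023, LIF from -0.17 to 0.088, sex chromosomes from -0.039 to 0.079, telomeres from -0.018 to 0.034 and naive genes from -0.13 to 0.19. Genes near background, such as Uba7, are limited by signal over background, and the offset of 50 in normexp shrinks their differences by construction. Of 66 genes taken by the naming rule, 24 differences were smaller and 1 larger with normexp by a factor over 1.5, and 1 turned direction. With slide row as a block 12 were smaller, 14 larger and 2 turned, with OSKH 2 and 3 alone 16, 3 and 2, with the replicate block 6, 2 and 0, and with single arrays left out up to 6, 4 and 3. Between 51.4% and 59.0% of probes were well above background.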

Other observations

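Genes high on single arrays were chosen after their values were seen and are given as log2 differences to the median of the other 7 arrays. On OSKH 1, Chac1 was at 2.90, Ddit3 at 2.88, Atf3 at 2.38 and Gdf15 at 2.59, genes known from the integrated stress response. Some members of the fixed stress list did not follow: the log2 signals of Hspa5 (5.93) and Xbp1 (4.29) were the lowest of the 8 arrays there. The list had a mean log2 signal of 3.74 on OSKH 1 and 2.85 to 3.15 on the others. Lyz2, a lysozyme known from macrophages and measured on 2 of 3 OSK arrays, was at 2.98 on OSKH 1 and 2.57 on ESC. On OSKH 3, Ndufa4l2 was at 3.82, Adm at 2.19, Egln3 at 1.81 and Bnip3 at 1.61, genes known to be induced by low oxygen, while Hk2, of the same fixed list, had its lowest log2 signal there (3.20). The hypoxia list had a mean log2 signal of 3.32 on OSKH 3 and 2.52 to 2.89 on the others. On OSK 2, Zscan4f, a marker of the 2-cell-like state, was at 3.43, with OSKH 2 at 2.11 and OSK 1 at 1.64. Chd3, a chromatin remodeller, was at 3.46 on OSK 2 and between -0.67 and 0.77 on the others.

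Some genes were high on both ESC and OSKH 4, which share a slide column. Col1a1 was at 2.52 on ESC and 2.90 on OSKH 4, Ccl2 at 3.11 and 2.22 (with OSKH 1 at 1.31), and Foxa2, measured on 2 of 3 OSK arrays, at 3.66 and 6.89.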
